A study of Mus musculus with 12 samples.

How the data were processed

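RNA was measured in C2C12 cells, an immortalised mouse myoblast line that fuses into myotubes after serum is lowered. Per the labels, cells grew in 10% fetal bovine serum to 80 to 90% confluence (proliferation) and were then kept in 2% horse serum for 2, 5 or 8 days. 3 independent experiments were recorded for each stage, which gave 12 arrays in 4 groups of 3 replicates. The labels do not say how far the cultures of an experiment were separate, so p values measure the spread between these arrays. Total RNA was extracted with Trizol, and 1 µg per sample was amplified and labelled with Cy3 on a one-colour Agilent array of custom design, per the labels' protocols.

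Each deposited file is the scanner output of 1 array, read with Agilent Feature Extraction 10.5.1.1 per the submitters' processing notes. The column used holds the processed signal of the green channel, an intensity in scanner units after the background treatment of that software, per the file headers. No normalization between arrays is recorded in the file headers. Each array carried 39448 spots, of which 1417 were controls, and 37831 spots of 37246 probes were used after controls and 200 negative-probe spots were set aside. Between 56.9% and 69.5% of these spots per array were well above background by the scanner's flag, and the 75th percentile of the signal lay between 1295 and 1993. 0 spots were saturated. The median of the negative-probe spots was 6.25, 5.39 and 2.42 on proliferation arrays 1, 2 and 3 and lay between 1.39 and 3.53 on later arrays. A fall on a probe near background was not told apart from this difference in level. The number of arrays limits the precision.

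The deposited intensity was converted here to log2, spots of a probe were averaged without spots flagged as population outliers, and the 75th percentile of each array was subtracted. Spots flagged as non-uniform, which made up 19.8% to 28.3% of spots per array, were kept, although flagged spots are normally left out. Among the brightest 10% of spots the flag fell on 42.9% to 49.5% on proliferation arrays and on 53.9% to 70.8% on later arrays. Leaving them out would thus have removed mainly bright probes, and more of them at the later stages. Among bright single-spot probes, those flagged on all arrays of a stage had a larger median SD than those flagged on none at proliferation (0.194 against 0.156), day 2 (0.169 against 0.135) and day 5 (0.149 against 0.115). At day 8 the values were 0.165 and 0.172. The choice to keep these spots was made after the data were examined, and both ways of leaving them out were run as alternatives.

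A probe was tested when it was well above background on all 3 arrays of at least 1 stage, which left 22959 probes. They were compared with limma (lmFit and eBayes, version 3.58.1, in R 4.3.3) in a single fit of stage means over the 12 arrays, with Benjamini-Hochberg adjusted p under 0.05 as the threshold for a change. Each later stage was compared with proliferation, day 5 with day 2 and day 8 with day 5, and an F test asked for any change across the 4 stages. Errors given with log2 fold changes are standard errors of this fit, with n = 3 arrays per stage. Tables were handled with the R package data.table (version 1.17.8), and plots were drawn with matplotlib (version 3.10.9, Python 3.11.15).

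Probe classes came from the accessions in the files: 22522 mRNA probes and a non-coding set of 14724 probes. The latter holds 316 curated non-coding RNAs, 13446 other transcripts known by AK, uc or similar accessions and 962 ultraconserved elements. Nothing in the files or the reference table used here shows that each of the other transcripts is non-coding. Accessions were given symbols through a reference table of the mouse assembly GRCm38.p6, used for names and gene types only. 22216 probes of 19259 symbols were named, and 89 of the non-coding RNA probes belong to genes marked there as lncRNA. The array header names build mm9, and no coordinates are given. A gene was represented by its tested probe with the highest mean signal. Of 13742 tested symbols, 1655 had several tested probes, and for 32 of them probes were called in opposite directions at day 8.

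Where a probe was not well above background on any array of a stage, the change is given as "at least N-fold". This bound sets the mean of the brighter stage against the mean, over the dim stage's arrays, of the higher of 2 signals: the lowest among probes well above background on that array, and the probe's own. A probe well above background on 1 or 2 arrays of a stage keeps its plain fold, which then rests in part on signals near background.

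21 gene lists were fixed before the data were examined, together with the design, the processing choices to vary and the rule for named genes. They cover myogenic factors, sarcomere, fusion, calcium handling and neuromuscular junction, muscle metabolism, S phase, mitosis, cell cycle inhibitors, Id and Notch genes, extracellular matrix, muscle lncRNAs, imprinted domains, unfolded protein and heat shock, interferon response, ubiquitin-linked atrophy, markers of adipocytes, osteoblasts, macrophages, endothelium and neural cells, and control genes. 19 of them had at least 5 tested members and were tested with limma's camera against the other genes (preset correlation 0.01, two-sided, adjusted over the lists of a comparison). The adipocyte and endothelial markers had 4 tested members each and are given as counts. Other listed markers were on the array but not well above background on all 3 arrays of any stage. Among these were the adipocyte markers Adipoq, Fabp4 and Plin1 and the endothelial markers Cldn5, Tie1 and Vwf. camera was repeated with an estimated correlation, and limma's fry asked whether each list moved on balance in a direction, without comparing it with other genes. fry gave an adjusted p under 0.05 in the same direction for 4 of 4, 8 of 8, 8 of 8, 9 of 9 and 2 of 3 of the lists called by camera at day 2, day 5 and day 8 against proliferation, day 5 against day 2 and day 8 against day 5.

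By the rule for named genes, each comparison with proliferation took up to 4 called members per list with the largest changes and no overlap between the arrays of the 2 stages. It also took the tested members of the myogenic factors and the muscle lncRNAs, and the 5 largest rises and 5 largest falls among mRNA probes and among the non-coding set, of probes well above background on at least 1 array of each stage. The 2 steps between later stages took their 5 largest rises and falls by the same rule. From these, the text gives the largest changes of each list, whether or not they held under the alternatives; this narrowing was made after the data were examined. Some genes that the rule takes are not reported here; they stayed in the tests of the lists. Neat1 in the last step, Bub1b at day 2, and Kis2, Snhg3, Norad and Peg13 at day 8 were singled out after their values were seen.

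The 12 arrays lie on 3 slides of 4, each scanned as a batch: proliferation with day 2 array 1, then day 2 arrays 2 and 3 with day 5 arrays 1 and 2, then day 5 array 3 with day 8. The slide was therefore run as a fixed block. With the block, day 2 against proliferation, day 5 against day 2 and day 8 against day 5 rest on the slide holding both stages, which has 1 day 2 array in the first and 1 day 5 array in the last of these. The day 5 and day 8 comparisons with proliferation chain these steps across slides. Other settings chosen then were quantile normalization, a percentile over probes above background on all arrays, other filters on dim probes, a trended and robust variance, fits of the 2 stages alone, a 2-fold minimum, the replicate number as a block, the slide as a block, each array left out in turn, all probes of a gene in place of 1, and the estimated correlation. Settings added after the data were examined were normexp background correction (offset 50), both treatments of non-uniform spots, the slide as a random block, and the data without the 2 arrays that lie on another slide than the rest of their stage. normexp had been planned on the mean signal. That planned setting could not be run with the columns used here, and normexp on the median signal took its place.

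The fit was checked on simulated data for the 22959 probes, with 200 probes changed by a known fold. At day 2, 7.46%, 35.8% and 77.3% of probes changed by 1.5-fold, 2-fold and 4-fold were called; at day 8 against day 5 these shares were 11.9%, 44.8% and 81.8%. False calls made up 4.65% to 7.22% of the calls over the 5 comparisons. The simulation drew independent noise for each array without a slide effect, so it does not bear on the overlap of stage and slide. In the real data 2920 to 12598 probes were called per comparison, so the adjustment for many tests acted differently there. The shares called are therefore not the power of the real fit.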

Results

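The series followed long non-coding and protein-coding transcripts while C2C12 myoblasts, a mouse muscle precursor line, left proliferation and differentiated. RNA from proliferating cells and from cells 2, 5 and 8 days after the switch to horse serum was hybridised to 12 one-colour arrays, 3 per stage. Signals correlated across probes at 0.985 to 0.994 between arrays of a stage and at 0.929 to 0.985 between arrays of different stages. Of the 22959 probes tested, 15103 (65.8%) changed across the 4 stages in limma's F test, and 7249 did so with the slide as a block. Among the tested probes were 16269 mRNA probes (72.2% of those on the array) and 6690 probes of the non-coding set (45.4%). The first principal component held 61.0% of the variance and ordered the stages from proliferation to day 8, and the second held 12.9%.

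**Figure D1:**
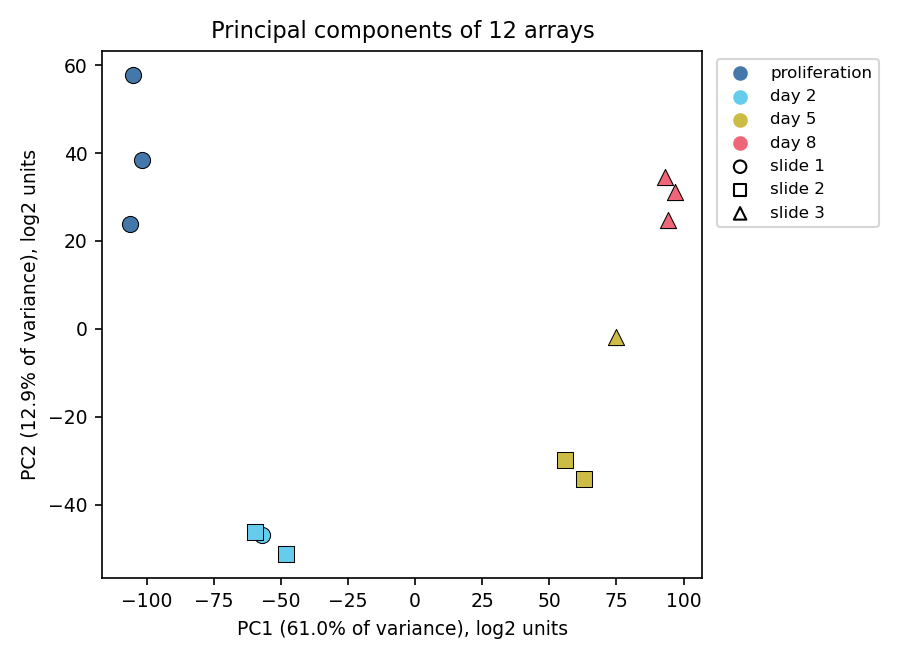
First and second principal components of the log2 signals of 12 arrays (axes in log2 units; colour marks the stage and symbol shape the slide). Proliferation and day 2 arrays lie at negative values of the first component (61.0% of the variance), day 5 and day 8 arrays at positive values, and of the day 5 arrays the one on the slide of day 8 lies nearest to the day 8 arrays (first component 74.87, second -1.93).

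Day 2 against proliferation asked what changed first after serum was lowered. Myogenin (Myog), the transcription factor that starts terminal muscle differentiation, rose 7.05-fold (log2 fold change 2.82 ± 0.24 SE, n = 3 arrays per stage, limma adjusted p = 3.2e-05). Contractile genes rose with it: Mybph, a myosin-binding protein, by 3.48 ± 0.21 and Myh3, the embryonic myosin heavy chain, by 3.40 ± 0.21 on the log2 scale. Id2, an inhibitor of myogenic helix-loop-helix factors, fell by 2.94 ± 0.17. Cilp, a cartilage matrix protein, rose 28.8-fold and Sprr2h, a cornified envelope gene, fell (-4.13 ± 0.35).

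29 of 45 measured sarcomere genes rose at day 2 and 1 fell (30 and 2 adjusted over the list alone), with a median of 1.23 (1.44 within the slide holding both stages). The gene that fell was Neb, whose probe was below background at both stages. camera placed the list above other genes (adjusted p = 1.47e-08; adjusted p = 0.322 with an estimated correlation). Of 25 genes of calcium handling and the neuromuscular junction, 13 rose and Musk, the agrin receptor kinase, fell (13 and 2 over the list alone; median 0.74, 0.90 within slide). Hrc, a calcium-binding protein of the sarcoplasmic reticulum, rose by 2.38 ± 0.18 and Chrng, the fetal acetylcholine receptor subunit, by 2.37 ± 0.20. This list had an adjusted p = 0.0159 in camera, adjusted p = 0.444 with an estimated correlation and 0.191 when all probes of a gene were used. Interferon-response genes were higher too: 9 of 16 rose (12 over the list alone; median 0.95, 1.01 within slide), led by Gbp2, a guanylate-binding GTPase (2.04 ± 0.24), and Irf7, a transcription factor of the interferon pathway (1.71 ± 0.13). Their camera adjusted p was 0.000327, with adjusted p = 0.11 with an estimated correlation.

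S-phase genes were lower at day 2: 6 of 25 fell and E2f2, a transcription factor of the cell cycle, rose (5 and 1 over the list alone; median -0.33, -0.24 within slide). The list had a camera adjusted p = 0.00717, and adjusted p = 0.444 with an estimated correlation. Mcm3, a subunit of the replicative helicase, fell by 1.45 ± 0.29, and this call was lost with the slide as a block (-0.68, adjusted p = 0.1; 0.000407 to 0.1 over its alternatives). Pola1, the catalytic subunit of DNA polymerase alpha, fell by 1.22 ± 0.23. Of 27 mitotic genes, 4 fell and Bub1b, a spindle checkpoint kinase, rose; over the list alone 2 fell. The mitotic median was -0.20 (-0.28 within slide) and camera did not call the list (adjusted p = 0.122; 0.0402 with quantile normalization and 0.0292 with all probes). The largest mitotic fall, of the kinetochore motor Cenpe (-0.61 ± 0.20), was lost without proliferation array 1 (adjusted p = 0.125) or 2 (0.0613), day 2 array 1 (0.105) or 3 (0.0993) or day 5 array 1 (0.0503). It was also lost under 2 of 6 other settings, among them the slide block (0.0938), over a range of 0.0248 to 0.125. The Bub1b rise (0.54 ± 0.17) was lost without proliferation array 1 (0.0835), 2 (0.0782) or 3 (0.0657) or day 2 array 2 (0.113) or 3 (0.0931), with the slide block (0.391), with quantile normalization (0.116) and with the percentile over probes above background on all arrays (0.0787), over a range of 0.0169 to 0.391.

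Among 10 myogenic factors, Myog and Pax7, a satellite cell factor (0.56 ± 0.16), rose and Myod1, the myogenic determination factor (-0.52 ± 0.17), fell; the list's median was -0.04 (0.09 within slide) and its mean 0.18, and camera pointed down without a call (adjusted p = 0.808). The Pax7 call was lost without proliferation array 1 (0.0549) or 2 (0.0676) or day 2 array 1 (0.0745) or 2 (0.0558) and with the slide block (0.0806; 0.00921 to 0.0806 over its alternatives). The Myod1 call was lost without proliferation array 2 (0.11) or 3 (0.105), day 2 array 1 (0.0511), 2 (0.0881) or 3 (0.102) or day 8 array 1 (0.0503). It was also lost under 5 of 8 other settings, over a range of 0.00125 to 0.963. Among these were the slide block (0.298), normexp (0.256) and the fits without non-uniform spots (0.963, or 0.121 with the percentile from all spots). Uncalled were Mef2a (-0.47; adjusted p = 0.411, but 0.0339 without day 2 array 1, within 0.0339 to 0.806 over its alternatives), Mef2c (-0.52), Six4 (-0.34), Myf5 (-0.06), Mef2d (-0.02) and Myf6 (0.06).

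The other lists were not called by camera at day 2. Muscle metabolism had 9 rises and 2 falls among 19 genes (the same counts over the list alone), with Ckm, the muscle creatine kinase, up by 2.80 ± 0.23 (adjusted p of the list 0.109). Extracellular matrix had 9 rises and 4 falls of 26 (11 and 4 over the list alone), with the proteoglycan Dcn up by 1.89 ± 0.19. In the Id and Notch list, 6 of 17 rose and 4 fell (7 and 5 over the list alone), with a median of 0.27 that was -0.01 within slide; Heyl, a Notch target repressor, rose by 3.54 ± 0.25. Fusion genes had 4 rises and 2 falls of 13, the metalloprotease Adam12 falling by 1.72 ± 0.27 and Mymk, the membrane activator of myoblast fusion, rising by 1.60 ± 0.18. Ubiquitin-linked atrophy had 6 rises and 1 fall of 12 (7 and 1 over the list alone), led by the ubiquitin ligase gene Fbxo32 (1.50 ± 0.15). Cell cycle inhibitors had 4 rises of 12 (6 over the list alone), led by Cdkn1c (2.14-fold, SE 0.27 on the log2 scale; lost with the slide block, adjusted p = 0.0881, and with the median over its probes, 0.0782; 0.00646 to 0.0881 over its alternatives). Imprinted genes had 5 rises and 1 fall of 13, led by Mest (1.79 ± 0.36), and unfolded-protein and heat-shock genes 4 rises of 18.

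Markers of other cell types were measured beside these groups. 2 of 6 macrophage markers rose, led by Aif1 (1.54 ± 0.29), 2 of 8 neural markers rose, led by Tubb3 (0.92 ± 0.20), 1 of 8 osteoblast markers fell, 3 of 4 adipocyte markers fell and 1 of 4 endothelial markers rose (Tek, 2.54 ± 0.17) while 1 fell. The osteoblast marker was Phex (-0.73 ± 0.19), a call lost without proliferation array 2 (0.0537) or day 2 array 1 (0.0517) or 2 (0.0557), with normexp (0.0537), with the slide block (0.0503) and without non-uniform spots (0.774), over a range of 0.00508 to 0.774. Of 13 control genes, Tfrc (-0.97 ± 0.15; adjusted p = 0.13 with the median over its probes, 0.000643 to 0.13 over its alternatives) and Hprt fell, and the list's median was 0.12 and its mean 0.01 while camera pointed down without a call. The Hprt fall (-0.41 ± 0.13) was lost without any of the 6 arrays compared (proliferation 1, 2 and 3 at 0.0547, 0.0823 and 0.0776, day 2 1, 2 and 3 at 0.0543, 0.0851 and 0.0818), with normexp (0.479) and with the slide block (0.21), over a range of 0.0058 to 0.479.

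Of the 6 measured members of the muscle lncRNA list, 5 had probes of the lncRNA and Sra1 a probe of its protein-coding mRNA. Neat1, the scaffold of paraspeckles, fell 2.97-fold at day 2 (-1.57 ± 0.26, adjusted p = 0.00165) and Snhg1, a host of small nucleolar RNAs, fell by 0.55 ± 0.15. The Snhg1 call was lost without proliferation array 2 (0.0623) or day 2 array 1 (0.0597) and with the slide block (0.0502; 0.0111 to 0.0623 over its alternatives). Malat1, an abundant nuclear RNA, rose by 0.78 ± 0.16, a call lost with the slide block (0.0835; 0.000939 to 0.0835 over its alternatives). Tug1 had no call on its brighter probe (-0.30), while its second probe fell 1.75-fold (-0.81 ± 0.14, adjusted p = 0.00167). Miat (-0.66) and the Sra1 mRNA (0.34) had no call. Across the non-coding set 838 probes rose and 843 fell, 25.1% of those tested against 32.9% of mRNA probes. H2-K2, a transcribed pseudogene of the class I histocompatibility region, rose (3.17 ± 0.30), as did uc007bfa (3.07 ± 0.79; lost without proliferation array 1, adjusted p = 0.0551, or 2, 0.0525; 0.00373 to 0.0551 over its alternatives). The transcript AK017961 fell (-3.39 ± 0.95), a call lost without day 2 array 1 (0.0711) or 3 (0.0508), with normexp (0.163), with the slide block (0.0642) and without non-uniform spots (0.0842), over a range of 0.0108 to 0.163. The folds of Ckm, Aif1, H2-K2 and uc007bfa rest on a baseline near background, with probes well above it on 1 of 3 proliferation arrays; Cilp and AK017961 were so on 2, and AK017961 on 1 at day 2. Of 48 tested probes of genes marked as lncRNA, 5 rose and 13 fell.

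In all, 7029 probes changed at day 2, 4212 higher and 2817 lower (59.9% higher), and 9679 had an unadjusted p under 0.05. With the slide as a block 3550 changed, 3138 of them in both fits. The split was 73.0% higher with normexp, and without non-uniform spots it was 96.3% (67.6% with the percentile from all spots). With the percentile over probes above background on all arrays it was 50.1% (3493 higher and 3473 lower), with a median of all tested probes of -0.02. That median was 0.07 without this change, 0.20 with normexp, 0.73 without non-uniform spots, 0.05 with quantile normalization or the slide block and -0.125 with no filter on dim probes.

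**Figure D2:**
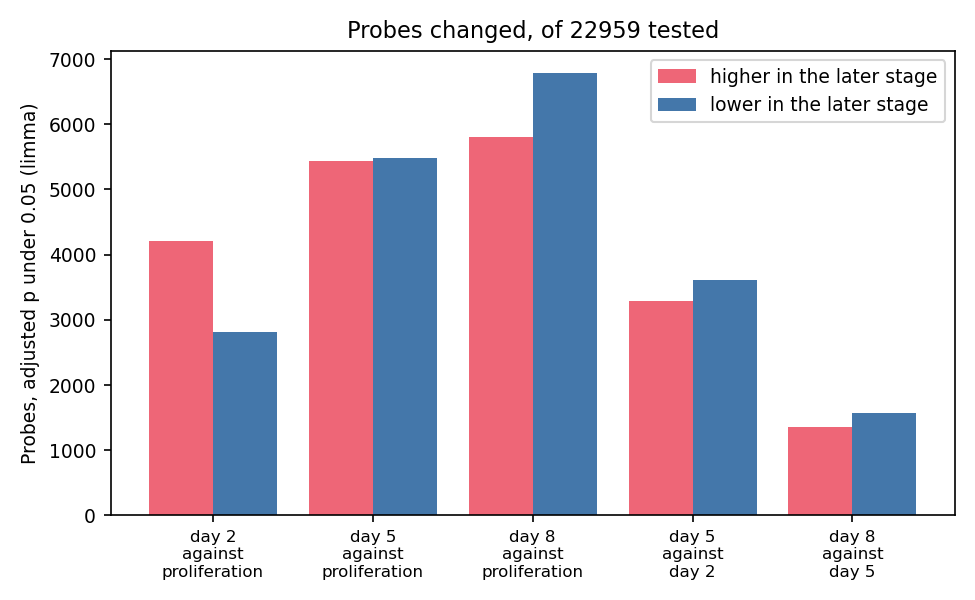
Number of probes with a limma adjusted p under 0.05 in each of 5 comparisons (vertical axis, of 22959 probes tested; red bars higher and blue bars lower in the later stage). The comparison of day 8 with proliferation has the tallest bars (5809 higher, 6789 lower) and that of day 8 with day 5 the shortest (1349 higher, 1571 lower).

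Day 5 against proliferation compared cells late in the switch to muscle genes with their starting state. Mb, the oxygen store myoglobin, rose 552-fold (9.11 ± 0.41), Myh3 334-fold (8.38 ± 0.21), Ckm 216-fold (7.75 ± 0.23) and Myog 185-fold (7.53 ± 0.24, adjusted p = 3.62e-09). Genes of replication and mitosis fell together, with Mcm3 at -4.27 ± 0.29 and Cenpe at -3.33 ± 0.20. Slc6a2, the noradrenaline transporter, rose by 8.04 ± 0.22, and the cornified envelope genes Sprr2h (-6.81 ± 0.35) and Lce1i (-6.50 ± 0.48) fell. At proliferation the probes of Mb, Ckm and Slc6a2, and further on those of Trim63, Ifit3 and Mx2, were well above background on 1 of 3 arrays, so these folds rest on a baseline near background. The falls of Sprr2h (1 of 3 day 5 arrays) and of Lce1i, uc008yem, Kdr and Tyrobp (2 of 3) end near background.

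41 of 45 sarcomere genes rose and Xirp2, an actin-binding repeat protein, fell (41 and 3 over the list alone; median 5.31, 5.76 with the slide block; camera adjusted p = 3.69e-22, and 0.0223 with an estimated correlation). Tnnc2, the fast troponin C, rose by 8.05 ± 0.27, and Mybpc2, a fast myosin-binding protein that was not well above background in proliferation, was at least 64.5-fold higher. All 20 calls among the 25 genes of calcium handling and the neuromuscular junction were rises (median 2.61, 2.61 with the block; adjusted p = 3.44e-11, 0.0223 with an estimated correlation), with Hrc at 7.24 ± 0.18 and Atp2a1, the fast calcium pump, at 6.22 ± 0.37. In muscle metabolism 11 of 19 rose, while Pdk4, a kinase that inhibits pyruvate dehydrogenase, and Ppargc1a, a coactivator of mitochondrial genes, fell (median 0.72, 0.90 with the block; adjusted p = 2e-04, 0.0394 with an estimated correlation).

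24 of 27 mitotic genes fell (25 over the list alone; median -2.65, -2.84 with the block; adjusted p = 3.74e-14, 0.0223 with an estimated correlation), and the kinetochore gene Ndc80 stood at -3.31 ± 0.50 next to Cenpe. 22 of 25 S-phase genes fell and E2f2 rose (24 and 1 over the list alone; median -1.80, -1.76 with the block; adjusted p = 7.18e-11, 0.0223 with an estimated correlation). Prim1, the catalytic primase subunit, fell by 3.12 ± 0.37.

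Extracellular matrix genes rose in 13 cases of 26 and fell in 4 (median 0.73, 1.02 with the block; camera adjusted p = 0.00803, adjusted p = 0.231 with an estimated correlation), with Col6a2, a collagen VI chain, at 5.37 ± 0.16 and Dcn at 4.38 ± 0.19. Of 16 interferon-response genes, 9 rose and 3 fell (11 and 3 over the list alone; median 1.01, 0.98 with the block; camera adjusted p = 0.00803, adjusted p = 0.0809 with an estimated correlation). Ifit3 (2.33 ± 0.17) and Mx2, on a probe of a record marked as transcribed pseudogene (2.00 ± 0.23), rose, and Ifit2, Rsad2 and Stat2, also interferon-induced genes, fell. The Rsad2 fall (-1.78 ± 0.45), on a probe below background at both stages, had the opposite sign with normexp (0.20, adjusted p = 0.299) and was lost with the slide block (0.41) and without non-uniform spots (0.0846; 0.00437 to 0.41 over its alternatives). Ubiquitin-linked atrophy genes had 8 rises and 1 fall of 12 (median 0.79, 1.02 with the block; camera adjusted p = 0.00153, adjusted p = 0.0608 with an estimated correlation), led by the muscle ubiquitin ligases Trim63 (4.01 ± 0.29) and Trim54 (3.27 ± 0.12). Counts over these lists alone were the same for matrix and atrophy.

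Of the myogenic factors, Myog, Pax7 (1.11 ± 0.16), Myod1 (0.93 ± 0.17) and Mef2c (0.73 ± 0.22) rose and Myf5 (-0.39 ± 0.15) fell at day 5; camera did not call the list (adjusted p = 0.262). The Mef2c call was lost without proliferation array 2 (0.0655) or day 5 array 1 (0.0738), with normexp (0.0555) and with the slide block (0.363; 0.000808 to 0.363 over its alternatives). The Myf5 call was lost without proliferation array 1 (0.114), 2 (0.083) or 3 (0.0759), day 2 array 2 (0.0593), day 5 array 2 (0.132) or 3 (0.108) or day 8 array 1 (0.0568) or 3 (0.0563). It was also lost under 3 of 6 other settings, among them normexp (0.32) and the slide block (0.113), over a range of 0.0342 to 0.32. Mef2a (-0.67), Myf6 (-0.29), Six4 (-0.28) and Mef2d (-0.23) had no call.

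Lists without a camera call at day 5 included fusion (7 rises and 2 falls of 13), in which Mymk rose by 5.93 ± 0.18, and cell cycle inhibitors (7 and 2 of 12), in which the p21 gene Cdkn1a rose by 1.69 ± 0.26. The Id and Notch list had 5 rises and 5 falls of 17 (6 and 5 over the list alone), with Heyl at 5.05 ± 0.25 and Id2 at -2.34 ± 0.17. Imprinted genes had 6 rises and 3 falls of 13, among them Igf2, a fetal growth factor, at 5.08 ± 0.29. Unfolded-protein and heat-shock genes had 5 rises and 2 falls of 18, and the small heat-shock gene Hspb7 was at least 24.4-fold higher. Control genes had 1 rise and 5 falls of 13 (1 and 6 over the list alone), with Tfrc at -1.51 ± 0.15.

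Among markers of other cell types at day 5, 4 of 8 neural markers fell, led by the neurofilament gene Nefl (-4.54 ± 0.16); camera gave the list an adjusted p = 0.0631, 0.0404 with all probes, and 0.05 and 0.0332 without proliferation array 1 and day 5 array 2. 2 of 6 macrophage markers rose and 4 fell, led by Tyrobp (-2.49 ± 0.64), whose call was lost with normexp (0.135) and with the slide block (0.442; 0.00317 to 0.442 over its alternatives). 1 osteoblast marker rose and 4 fell (1 and 5 over the list alone), led by Dmp1 (1.68 ± 0.26; lost with the slide block, 0.0861; 2.28e-05 to 0.0861 over its alternatives). 1 adipocyte marker rose and 2 fell, led by the lipid droplet gene Plin4 (-1.78 ± 0.14), and 1 endothelial marker rose and 2 fell, led by the VEGF receptor Kdr (-2.92 ± 0.26).

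Of the muscle lncRNA list at day 5, Snhg1 fell (-1.04 ± 0.15) and Neat1 fell by 0.93 ± 0.26, the latter call being lost without proliferation array 1 (0.0522) or 2 (0.0507) or day 5 array 1 (0.0516) and with the slide block (0.103; 0.00286 to 0.103 over its alternatives). Tug1 rose 2.02-fold (1.01 ± 0.17; 0.30 without a call on its second probe) and Malat1 by 0.57 ± 0.16; both calls were lost with the slide block (0.0511 and 0.418, over ranges of 7.2e-05 to 0.0511 and 0.00123 to 0.418). Miat (-0.21) and the Sra1 mRNA (0.19) had no call, and the list's median (-0.01) and mean (-0.07) lay below 0 while camera pointed up without a call (0.958). In the non-coding set 1313 probes rose and 1398 fell, 40.5% of those tested against 50.4% of mRNA probes. Among these, uc009sqw (6.75 ± 0.20) and uc009use (6.30 ± 0.22) rose, and AK015549 (-5.39 ± 0.27) and uc008yem (-4.30 ± 0.45) fell. Of the probes of genes marked as lncRNA, 9 rose and 15 fell.

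At day 5, 10917 probes changed, 5440 higher and 5477 lower (49.8% higher), with 12431 at an unadjusted p under 0.05. With the slide as a block 5217 changed, 4863 of them in both fits. The share of higher probes was 60.2% with normexp and 88.6% without non-uniform spots (53.4% with the percentile from all spots), and the median of all tested probes was -0.02, against 0.14 with normexp, 0.80 without non-uniform spots and -0.32 with no filter on dim probes (47.2% higher).

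**Figure D3:**
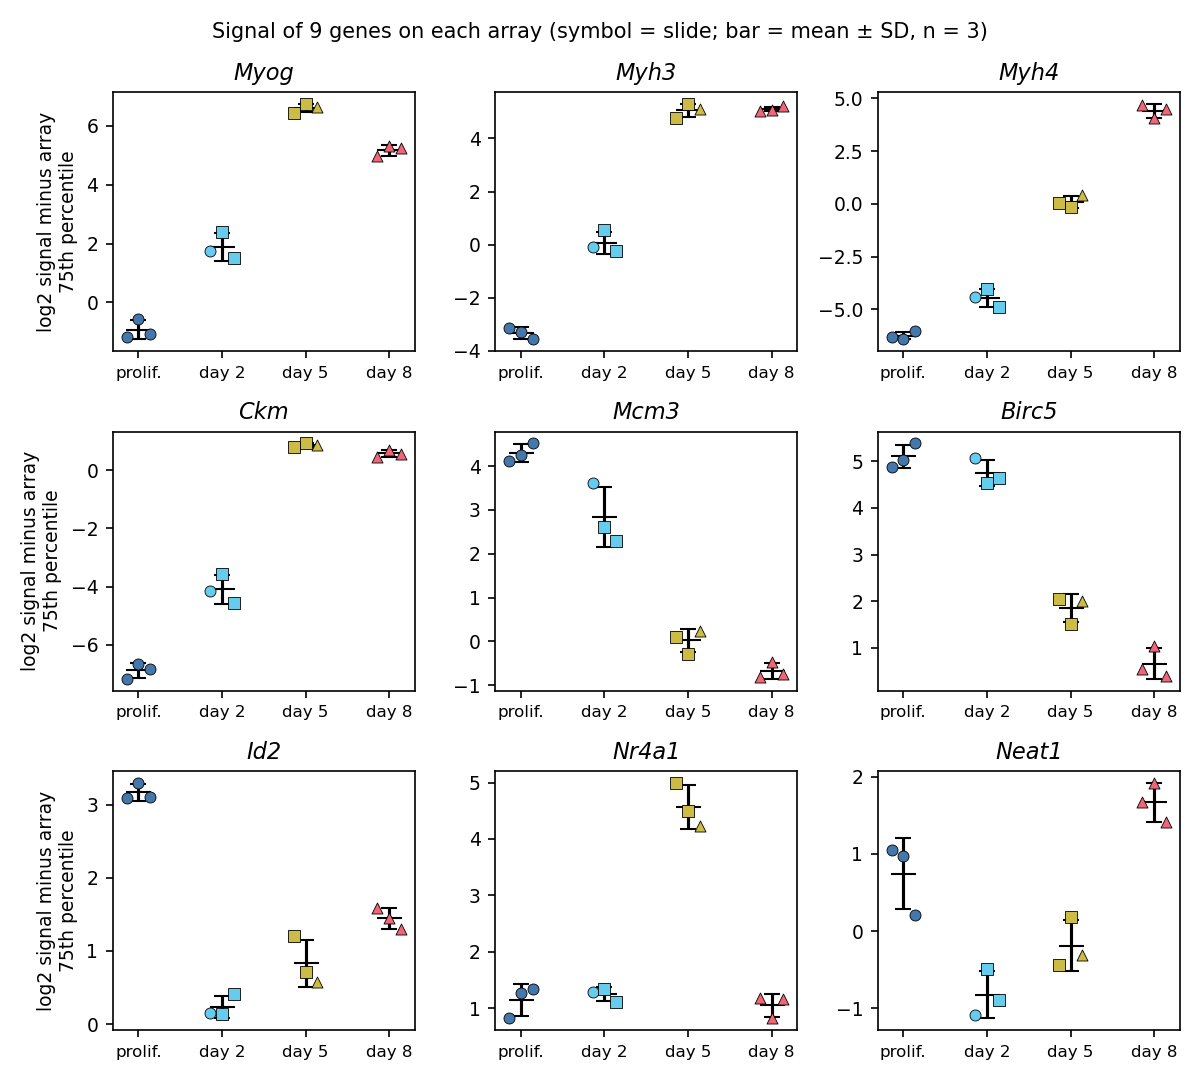
Signal of 9 genes on each array (vertical axis, log2 signal minus the array's 75th percentile; horizontal axis, stage; symbol shape marks the slide, bars give mean ± SD, n = 3). Myog and Myh3 are high from day 5 on, Myh4 is highest at day 8 (4.05 to 4.69), the means of Mcm3 and Birc5 decline from day 2 to day 8, and Nr4a1 is highest at day 5 (4.23 to 5.00).

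Day 8 against proliferation gave the span of the whole course. Myh4, the fast IIb myosin heavy chain, rose (10.65 ± 0.24, adjusted p = 8.89e-10), and Mybpc2 was at least 136-fold higher. Cilp rose 766-fold (9.58 ± 0.44) and Igf1, a growth factor for muscle, 708-fold (9.47 ± 0.31). Myog was 68.7-fold higher (6.10 ± 0.24). At proliferation the probes of Myh4 and Igf1, and further on those of Mb, Ckm, Myl2, Trim63, Ifit3 and Aif1, were well above background on 1 of 3 arrays and those of Cilp, Isg15 and AK020587 on 2, so these folds rest on a baseline near background. The falls of Kdr and uc007axg (1 of 3 day 8 arrays) and Cdh5 (2 of 3) end near background. All 27 measured mitotic genes fell, with Birc5, the inhibitor of apoptosis survivin, at -4.44 ± 0.23, and 24 of 25 S-phase genes fell, with Mcm3 at -4.96 ± 0.29 and Tk1, thymidine kinase, at -4.35 ± 0.18.

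Sarcomere genes rose in 41 cases of 45, and Tmod4, Tpm1 and Xirp2, which also encode actin-linked muscle proteins, fell (median 5.57, 5.94 with the slide block; camera adjusted p = 9.02e-23, 0.0184 with an estimated correlation). Myl2, a slow myosin light chain, rose by 8.74 ± 0.33. In calcium handling and the neuromuscular junction 20 of 25 rose and the calcium channel gene Cacna1s fell (median 2.40, 2.5 with the block; adjusted p = 2.69e-10, 0.0184 with an estimated correlation), led by Hrc (166-fold) and Casq1, calsequestrin (128-fold, SE 0.16 on the log2 scale). In muscle metabolism 12 of 19 rose and Ppargc1a fell (median 0.94, 1.16 with the block; adjusted p = 1.09e-05, 0.0184 with an estimated correlation), with Mb at 8.79 ± 0.41 and Ckm at 7.47 ± 0.23. Mitosis had a median of -3.25 (-3.54 with the block; adjusted p = 4.48e-14) and S phase of -2.49 (-2.57 with the block; adjusted p = 1.99e-12); both had 0.0184 with an estimated correlation, and all 25 S-phase genes fell over the list alone. Ndc80 fell by 4.03 ± 0.50.

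10 of 16 interferon-response genes rose at day 8 (median 1.11, 1.20 with the block; adjusted p = 0.000631, 0.032 with an estimated correlation), led by Ifit3 (3.15 ± 0.17) and Isg15, a ubiquitin-like modifier (2.12 ± 0.23). Extracellular matrix had 14 rises and 6 falls of 26 (median 0.73, 1.11 with the block; camera adjusted p = 0.0053, adjusted p = 0.21 with an estimated correlation), with Col6a2 at 5.73 ± 0.16 and Dcn at 4.64 ± 0.19. Among those that fell were the collagen genes Col1a1 and Col4a2, the metalloprotease gene Mmp9 and its inhibitor Timp1. Ubiquitin-linked atrophy genes had 7 rises and 1 fall of 12 (median 0.57, 0.71 with the block; camera adjusted p = 0.00542, adjusted p = 0.092 with an estimated correlation), led by Trim63 (4.01 ± 0.29) and Klf15, a glucocorticoid-induced transcription factor (3.90 ± 0.24). For the called lists other than S phase, the counts over the list alone were the same at day 8.

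Of the myogenic factors at day 8, Myog, Mef2c (1.97 ± 0.22) and Pax7 (1.03 ± 0.16) rose and Myf5 (-0.47 ± 0.15) fell, with a camera adjusted p = 0.18 for the list. The Myf5 call was lost without proliferation array 1 (0.0542) or day 8 array 1 (0.068) or 3 (0.0678), with normexp (0.183) and with the slide block (0.21; 0.0105 to 0.21 over its alternatives). Myod1 had no call (0.35, adjusted p = 0.0985), but had one with quantile normalization (0.00115) and without day 8 array 2 (0.0329), within 0.00115 to 0.526 over its alternatives. Mef2a (-0.74, adjusted p = 0.149) had a call without day 2 array 1 (0.0361; 0.0361 to 0.872 over its alternatives). Six4 (-0.23), Myf6 (-0.14) and Mef2d (-0.00) had no call.

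Among the lists without a camera call at day 8, fusion had 5 rises and 2 falls of 13 (5 and 3 over the list alone), with Mymk at 5.75 ± 0.18, and cell cycle inhibitors had 6 rises, led by Gadd45a (2.07 ± 0.11), while Cdkn2d and Rbl1 fell. The Id and Notch list had 5 rises and 6 falls of 17, a median of -0.03 and a mean of 0.12, with Heyl at 3.90 ± 0.25 and Msc, a repressor of myogenic factors, at -2.83 ± 0.21. Imprinted genes had 5 rises and 3 falls of 13 (5 and 4 over the list alone), a median of -0.13 (0.59 with the block) and a mean of 0.11, with Igf2 at 4.54 ± 0.29. Unfolded-protein and heat-shock genes had 5 rises and 3 falls of 18, a median of -0.05 and a mean of 0.28, and Hspb7 was at least 48.6-fold higher. For these last 3 lists camera pointed up without a call. 2 control genes, B2m and Sdha, rose and 5 fell, with Tfrc at -1.31 ± 0.15.

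Markers of other cell types differed in direction at day 8. Of 6 macrophage markers, Aif1 (1.55 ± 0.29) and Csf1r rose and Cd14, Lyz2 and Tyrobp fell; with the slide as a block only the Aif1 call was kept (2.54, adjusted p = 0.0208). Tyrobp was lower by at least 5.53-fold, a call lost with normexp (0.324) and with the slide block (0.369; 0.000692 to 0.369 over its alternatives). Neural markers had 4 falls of 8 (median -0.56, 0.15 with the block), led by Nefl (-3.74 ± 0.16). Among osteoblast markers Dmp1 rose and Bglap fell, and neither was called over the list alone. The Dmp1 call was lost without proliferation array 2 (0.0951) or 3 (0.061) or day 8 array 2 (0.0998) and with the slide block (0.587; 0.00209 to 0.587 over its alternatives). The fall of Bglap (-1.06 ± 0.36) was lost without proliferation array 1 (0.106) or day 8 array 2 (0.0879) or 3 (0.0678) and with the slide block (0.117; 0.0116 to 0.117 over its alternatives). The adipocyte markers Plin4 (-2.12 ± 0.14) and Pparg fell, and among endothelial markers Tek rose while Kdr (-3.18 ± 0.26) and Cdh5 fell; the Cdh5 call was lost with normexp (0.276) and with the slide block (0.168; 8.75e-05 to 0.276 over its alternatives).

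Of the muscle lncRNA list at day 8, Tug1 rose 2.39-fold (1.26 ± 0.17); its second probe read 0.14, and the call was lost with the median over the probes (0.197; 1.26e-05 to 0.197 over its alternatives). Malat1 (1.04 ± 0.16) and Neat1 (0.92 ± 0.26) rose, and both calls were lost with the slide block (0.204 and 0.505, over ranges of 8.79e-05 to 0.204 and 0.00116 to 0.505). Snhg1 fell by 0.70 ± 0.15, a call lost with normexp (0.0908; 0.0011 to 0.0908 over its alternatives). Miat (-1.62 ± 0.71, adjusted p = 0.0741) had a call only without proliferation array 3 (0.03) or day 5 array 3 (0.0486), within 0.03 to 0.973, and the Sra1 mRNA (-0.26) only with normexp (0.0464), within 0.0464 to 0.769. In the non-coding set 1401 probes rose and 1878 fell, 49.0% of those tested against 57.3% of mRNA probes; uc009use (6.82 ± 0.22) and AK020587 (6.57 ± 0.22) were among those that rose, and AK015549 (-5.53 ± 0.27) and uc007axg (-5.41 ± 0.66) among those that fell. Among 158 tested probes of ultraconserved elements (16.4% of those on the array) 16 rose and 46 fell. These calls made up 39.2% of those tested, below the 49.0% of the whole non-coding set.

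Of the 48 probes of genes marked as lncRNA, 8 rose and 15 fell at day 8. Norad, a cytoplasmic RNA that binds Pumilio proteins, rose by 1.22 ± 0.18 and Snhg3, a host of small nucleolar RNAs, fell by 1.25 ± 0.11 (without non-uniform spots adjusted p = 0.112; 2.18e-06 to 0.112 over its alternatives). Peg13, an imprinted RNA, rose by 1.23 ± 0.17 and the lncRNA Kis2 fell by 2.70 ± 0.39; both calls were lost with the slide block (0.0528 and 0.237, over ranges of 4.89e-05 to 0.0528 and 1.85e-05 to 0.237).

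At day 8, 12598 probes changed, 5809 higher and 6789 lower (46.1% higher), with 13847 at an unadjusted p under 0.05. With the slide as a block 3993 changed (56.5% higher), 3682 of them in both fits, and 95.8% of the 12598 kept their direction. The share of higher probes was 60.5% with normexp and 79.8% without non-uniform spots (47.9% with the percentile from all spots), and the median of all tested probes was -0.12, against 0.15 with normexp, 0.02 with quantile normalization, 0.03 with the slide block, 0.51 without non-uniform spots and -0.52 with no filter on dim probes (41.4% higher, 5164 against 7322).

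**Figure D4:**
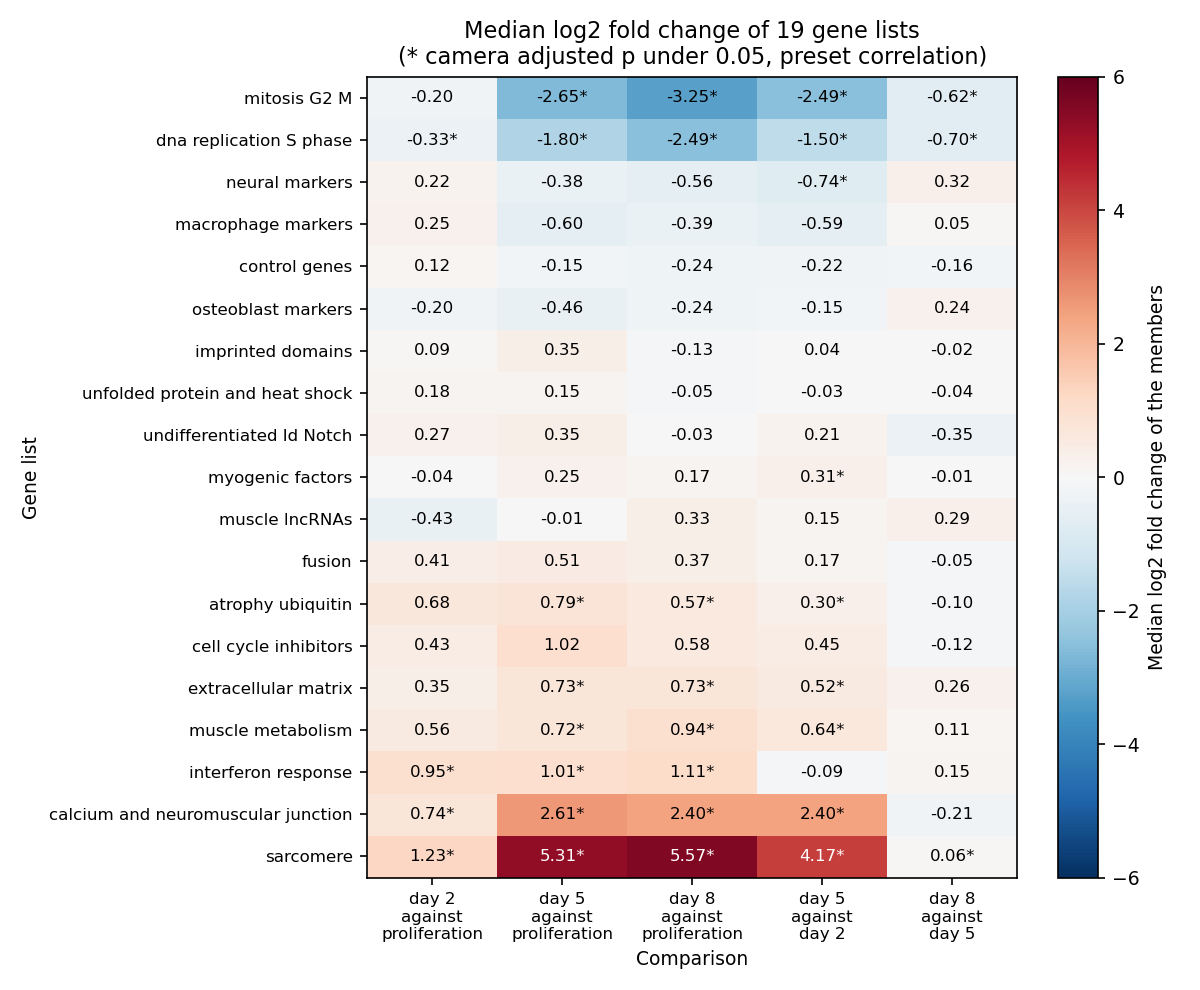
Median log2 fold change of the measured members of 19 gene lists (vertical axis) in 5 comparisons (horizontal axis); colour and printed value give the median, and an asterisk marks a camera adjusted p under 0.05 at the preset correlation. Sarcomere genes have the highest medians (5.31 at day 5, 5.57 at day 8) and mitotic genes the lowest (-2.65 and -3.25).

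Day 5 against day 2 isolated the middle step, on slide 2 for 4 of the 6 arrays. Mb rose by 7.10 ± 0.41, Mybpc2 by 6.20 ± 0.30, Myl2 by 5.94 ± 0.33, Actn2, the sarcomeric alpha-actinin, by 5.83 ± 0.41 and Tcap, a titin cap protein, by 5.79 ± 0.23. The neurofilament genes Nefl (-4.30 ± 0.16) and Nefm (-4.20 ± 0.20) fell, as did the mast cell protease gene Mcpt8 (-4.55 ± 0.21), the transcript NM_201366 (-4.46 ± 0.20) and the ubiquitin ligase gene Rnf183 (-4.39 ± 0.17). These 10 calls held with the slide as a block; the probes of Actn2 (1 of 3 day 2 arrays), Mybpc2 (2 of 3) and Rnf183 (2 of 3 at day 5) were well above background on part of a stage.

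40 of 45 sarcomere genes rose and Xirp2 fell in this step (median 4.17, 4.06 within slide; camera adjusted p = 1.55e-32). 21 of 25 genes of calcium handling and the neuromuscular junction rose (23 over the list alone; median 2.40, 1.99 within slide; 1.97e-16), and in muscle metabolism 10 of 19 rose and 1 fell (median 0.64, 0.75 within slide; 1.19e-05). 24 of 27 mitotic genes (median -2.49, -2.54 within slide; 3.08e-17) and 21 of 25 S-phase genes (22 over the list alone; median -1.50, -1.55 within slide; 9.2e-12) fell. With an estimated correlation these 5 lists had adjusted p = 0.0104, 0.0104, 0.0188, 0.0164 and 0.0176 in that order.

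4 more lists were called in this step and lost with an estimated correlation. Extracellular matrix had 13 rises and 2 falls (15 and 4 over the list alone; median 0.52, 0.66 within slide; camera adjusted p = 0.00047, adjusted p = 0.0958 with an estimated correlation). Ubiquitin-linked atrophy had 4 rises of 12 (median 0.30, 0.25 within slide; 0.00377, adjusted p = 0.0888 with an estimated correlation). Of the myogenic factors 5 rose, among them Myog (4.71), Myod1 (1.46), Mef2c (1.25) and Pax7 (0.55) (median 0.31, 0.49 within slide; 0.0379, adjusted p = 0.0958 with an estimated correlation), a list call also lost without day 2 array 3 (0.0606) or day 5 array 3 (0.0608). Of the neural markers 4 fell, among them Nefl, Stmn2 and Tubb3 (median -0.74, -0.46 within slide; 0.0102, adjusted p = 0.0958 with an estimated correlation). camera pointed up without a call for the interferon list (median -0.09, 0.01 within slide, mean -0.11) and for unfolded-protein and heat-shock genes (median -0.03, mean 0.30).

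In this step 6908 probes changed, 3292 higher and 3616 lower (47.7% higher), with 9164 at an unadjusted p under 0.05. With the slide as a block 5080 changed, 4827 of them in both fits. The share of higher probes was 60.2% without non-uniform spots. The non-coding set had 914 rises and 733 falls, 24.6% of those tested against 32.3% of mRNA probes.

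Day 8 against day 5 gave the last step. Myh4 rose 19.9-fold (4.32 ± 0.24, adjusted p = 1.64e-05), Lgr5, a receptor for R-spondins, 11.8-fold (3.56 ± 0.15), and Angptl7, well above background on 1 of 3 day 5 arrays, by 3.56 ± 0.27; Gm5039 (3.38 ± 0.43) and AK149390 (2.79 ± 0.20) followed. The transcription factors of the immediate early response Nr4a1 (-3.52 ± 0.21), Atf3 (-3.09 ± 0.23) and Fos (-2.85 ± 0.18) fell, as did the transcripts AK081596 (-2.69 ± 0.34) and BC056623 (-2.57 ± 0.31). Neat1 rose 3.62-fold (1.85 ± 0.26, adjusted p = 0.00254; the highest over its alternatives was 0.0305, with the slide block, at 1.97). That block value rests on the 1 day 5 array of slide 3, with its spread taken from other groups.

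16 of 25 S-phase genes fell further (17 over the list alone; median -0.70, -0.88 within slide; camera adjusted p = 5.13e-09, adjusted p = 0.127 with an estimated correlation), as did 10 of 27 mitotic genes (14 over the list alone; median -0.62, -0.69 within slide; 1.17e-06, adjusted p = 0.294 with an estimated correlation). Within slide 5 S-phase and 2 mitotic genes were called lower. 8 sarcomere genes rose (Mybpc1, Mybpc2, Myh1, Myh2, Myh4, Myot, Myoz2 and Tcap) and the beta-tropomyosin gene Tpm2 fell, with a median of 0.06 and a mean of 0.38 (median 0.20 within slide). The sarcomere list had a camera adjusted p = 0.0418 and adjusted p = 0.616 with an estimated correlation. Its call was lost with the slide block (0.173), normexp (0.0865) or all probes (0.31), and without day 2 array 1 (0.0534), day 5 array 1 (0.127) or day 8 array 2 (0.139). Without a call, camera pointed down for calcium handling and neuromuscular junction (median -0.21, mean 0.11), and up for fusion (-0.05 and -0.05), macrophage markers (0.05 and -0.02), myogenic factors (-0.01 and -0.05) and unfolded-protein and heat-shock genes (-0.04 and -0.16).

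In this last step 2920 probes changed, 1349 higher and 1571 lower (46.2% higher), with 6730 at an unadjusted p under 0.05. Within slide 3, against its 1 day 5 array, 737 changed (59.2% higher), 498 of them in both fits. The share of higher probes was 57.1% with quantile normalization and 24.7% without non-uniform spots (50.2% with the percentile from all spots). It was 55.2% with the percentile over probes above background on all arrays (1595 higher and 1294 lower), and the median of all tested probes was -0.08, against 0.02 with normexp and -0.23 without non-uniform spots. The count was 1129, 1670 and 3437 without day 5 array 1, 2 and 3, and 1480, 1781 and 1475 without day 8 array 1, 2 and 3. The non-coding set had 314 rises and 418 falls, 10.9% of those tested against 13.4% of mRNA probes, and 2 of the probes of genes marked as lncRNA rose.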

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

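Of 328 named gene values, 306 of them called, 238 kept their direction and their side of the threshold under every setting and 90 did not; 276 did so apart from the slide block. Calls lost were 75 with the slide block, 22 with normexp, 2 with quantile normalization, 2 with the percentile over detected probes, 4 with the median over probes and, of 160 values measurable, 11 without non-uniform spots and 4 with the percentile from all spots. With any single array left out, 3 to 18 values changed. Opposite in sign were Rsad2 at day 5 with normexp (0.198 against -1.78) and Snap25 at day 8 with the slide block (0.355 against -0.86). The cause was not tested for either. The Rsad2 probe was not well above background on any array of the stages compared, and the level of negative-probe spots differed between those arrays. Without non-uniform spots Plin4 at day 2 (0.166 against -0.43) and Spp1 at day 5 (0.270 against -0.52) were opposite in sign. With the same spots left out but the percentile from all spots, 0 values were reversed. The Plin4 and Spp1 reversals thus came with the shift of the percentile. Of the list results, 542 were the same, 20 weaker and 8 stronger under other settings.

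With the slide block 3550, 5217, 3993 and 737 probes changed at day 2, day 5 and day 8 against proliferation and day 8 against day 5, and 7249 across stages. Standard errors were larger in that fit (median 0.204 against 0.270 at day 2 and 0.448 at day 8). A 2-fold minimum left 2499, 5902, 7225, 3422 and 1099 by construction. Without non-uniform spots 4448, 6324, 5758, 2080 and 279 changed and 7464 across stages, and with the percentile from all spots 3172, 5395, 6652, 3449, 1271 and 7856, with fewer probes measured. For day 8 against day 5 the count was 1834 with normexp, 1307 with no filter on dim probes and 1845 from the arrays of these 2 stages alone; the cause was not tested. With the slide as a random block it was 2566, and without the 2 arrays that lie apart from their stage's slide 3578. An estimated correlation left 0 camera calls at day 2 (2 unadjusted), 5 at day 5, 5 for day 5 against day 2 and 0 for day 8 against day 5 (2 unadjusted).

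Leaving out 1 array gave 5115 to 7342 probes at day 2, 9612 to 10988 at day 5, 11087 to 13009 at day 8, 5665 to 7189 for day 5 against day 2, 1129 to 3437 for day 8 against day 5 and 13649 to 15427 across stages. The list counts were then 4 throughout, 8 to 9, 8 throughout, 8 to 9 and 2 to 4. Fusion genes gained a camera call with all probes at day 5 (0.0349) and for day 5 against day 2 (0.0163, and 0.0469 with the slide block), as did cell cycle inhibitors with all probes at day 5 (0.0404). With an estimated correlation neither list was called in these comparisons. Deviations from the stage mean correlated at -0.156 to 0.243 between arrays of like replicate number and at -0.264 to 0.222 between unlike numbers. No pairing by number was seen, but with 3 arrays per stage it cannot be ruled out. With the number as a block 6769, 10823, 12474, 6668 and 2483 probes changed, and 5 named calls were lost. Signal over background limits the results to 22959 of 37246 probes.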

Other observations

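Gene groups outside the lists fixed at the start were drawn up as 8 further lists after the data were examined. Changes of their members had been seen by then, so their counts and medians are descriptive and no p value is given for any of them. Of the cholesterol synthesis genes, 16 of 18 rose at day 2 (median 1.50, 1.26 with the slide block), led by Mvd (2.09 ± 0.13) and the lanosterol synthase gene Lss (1.91 ± 0.15). Between day 2 and day 5 all 18 fell (median -1.17, -1.24 within slide), with Lss at -2.15 ± 0.15. Genes of ribosome biogenesis fell in 12 cases of 19 at day 2 (median -0.77, -0.72 with the block) and in 18 of 19 at day 8 (median -1.13, -1.02 with the block). The box C/D snoRNP genes Nop56 (-4.77 ± 0.41) and Nop58 (-3.22 ± 0.39) fell most at day 8.

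Class I antigen presentation rose at day 2 in 11 of 15 genes (median 0.94, 0.77 with the block), with the class I genes H2-T23 at 1.43 ± 0.34 and H2-Q4 at 1.43 ± 0.13. Notch pathway genes rose in 10 of 17 cases at day 2 (median 0.78, 0.74 with the block) and fell in 7 between day 5 and day 8 (median -0.56, -0.54 within slide). Cornified envelope genes fell in 14 of 18 cases at day 8 (median -2.16, -1.56 with the block and -0.98 with normexp), among them Lce1h and Sprr1a (-3.79 ± 0.18). Neuronal cytoskeleton genes fell in 7 of 11 cases between day 2 and day 5 and 1 rose (median -2.11, -1.98 within slide). For the IGF axis of 15 genes, 6 rose and 1 fell at day 2, 7 and 3 at day 5, 8 and 4 at day 8, and 6 and 5 between day 2 and day 5.

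Of the tests below, those on a single array, on slide differences and on macrophages were chosen after the result was seen, and their limits were set then. Immediate early genes, a list of 25 with 23 tested that was also drawn up after the data were examined, were higher at day 5 than at day 8: 13 fell in the last step (median -0.92), with Fosb at -2.44 ± 0.19. The rise was not confined to a single array: the lowest of the 3 day 5 arrays lay 0.50 above the highest array of any other stage. This describes a list drawn up from the same data. A shared culture or handling of these 3 arrays was not tested and stays open. The step up from day 2 (13 rose and 2 fell, median 0.67) was also present within slide 2, with 2 arrays of each stage. There the genes were 0.63 higher at day 5 and 20 of 23 were higher. A slide difference is not excluded by this, since the list and the limit were both set after these values were seen. A slide difference stays open for the step down to day 8 too, where slide 3 holds 1 day 5 array (median -0.86, 21 of 23 lower). Signal level also stays open, since setting a list drawn up after its falls were seen against 10000 lists matched on signal (0% as low) decides nothing. A hypothesis left open is that the day 5 cells were handled closer to a change of medium, which times of medium change could test.

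The interferon list was higher from day 2 on (median 0.95 at day 2), but with an estimated correlation camera called it at day 8 only. Within slide 1 the day 2 array lay 1.01 above proliferation with 15 of 16 genes higher, against 0.76 from the day 2 arrays of slide 2; this rests on 1 array, so a slide difference stays open. Of 10000 lists matched on signal 99.99% had a median at most as high (95% from -0.38 to 0.44), so signal level was excluded. Macrophages among the cells stayed open: 3 of 6 macrophage markers fell and 2 rose at day 8, but with the slide block only 1 was called, and it rose. The listed markers Adgre1, Itgam, Mrc1 and Ptprc were on the array but not well above background on all 3 arrays of any stage. They were therefore not tested. The serum switch itself was not separated from differentiation by any stage here.

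Probes of the non-coding set were called at day 8 less often than mRNA probes, by 8.27 percentage points. After mRNA probes were weighted to the same signal (20 bins) the gap was 7.59 points (95% bootstrap interval 6.06 to 9.04), so dim signal was excluded as the main cause. After weighting to the same residual SD it was 5.48 points (4.03 to 6.87), which left a larger spread between arrays open. No biological explanation was tested for this gap.

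The arrays of each comparison were also split in the 10 ways that keep 3 against 3, and 10 splits cannot give a share under 0.1. For probes, 1 split, the real one, reached the real count in each comparison: 7029 against at most 0 in limma in another split at day 2 (1698 unadjusted), 10917 against 0 at day 5 (1488 unadjusted), 12598 against 0 at day 8 (1110 unadjusted), 6908 against 4 for day 5 against day 2 and 2920 against 1 for day 8 against day 5. For lists, the real count and the highest other were 4 and 4 at day 2 (3 splits as large), 8 and 7 at day 5 (1), 8 and 7 at day 8 (1), 9 and 8 for day 5 against day 2 (1) and 3 and 4 for day 8 against day 5 (3). Each other split mixes the 2 stages, so part of the stage difference stays between its groups and the rest enters the residual spread. These counts therefore do not show what would be called without a stage difference, for probes or for lists. Across the 4 stages, 100 splits of the 12 arrays were compared, the real one among them and the rest drawn at random. Only the real one reached 15103, and the highest count of a drawn split was 2952. Within a stage, the 1 array lying on another slide differed from the other 2 at 196 probes at day 2 and 952 at day 5, which does not tell a slide from a single array.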
